A study of Mus musculus with 4 samples.

How the data were processed

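RNA of 4 samples was measured, 2 of wild-type and 2 of Ezh2 KO leukemic cells carrying MLL-AF9, purified from the marrow of recipient mice. Total RNA was extracted with Trizol and made into biotinylated cRNA, per the labels' protocols. The deposited values are probe set intensities on a linear scale. They came from Affymetrix Expression Console, per the submitters' processing notes, with the version and the summary algorithm not given in the sources used here. The scale was read from the values: the mean of each deposited array, trimmed by 2% at each end, was 500, and the arrays' quantiles differed, so no quantile normalization had been applied. Scaling each array to one trimmed mean removes any difference in the total amount of mRNA per cell. Sample groups and replicate numbers were taken from the sample titles.

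The table held 45101 probe sets. Of these, 64 were control probe sets and were left out, 34958 had 1 gene symbol in the platform's annotation, 932 had several and 9160 were not in the gene table. Of the probe sets with 1 symbol, 34754 matched the RefSeq genes of the mouse assembly GRCm38.p6 by their gene identifier, which changed 0 symbols, and 204 kept the annotation's symbol. Only probe sets with 1 symbol entered the comparison. Each of 18193 genes was represented by its probe set of highest mean, and 13916 genes whose mean exceeded the 30th percentile of the non-control probe sets, an intensity of 19.96, were tested. Detection calls were not used here, so an intensity near that limit cannot be told from background. The positions of probes were not analysed here.

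Values were tested as log2(intensity + 16) without further normalization, using lmFit and eBayes of limma 3.58.1 in R 4.3.3 with a prior variance that follows mean intensity. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Folds are on the scale of intensity plus 16, which understates the change of dim genes. Each gene had 2 residual degrees of freedom, and 9.56 with the prior. Among the 1608 changed genes, 956 had a further probe set above the filter. In 318 of these a further probe set also changed in the same direction, and in 2 one changed in the opposite direction.

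The 30 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Ezh2, the 12 largest rises and 12 largest falls among changed genes whose groups did not overlap, and of each list up to 4 changed members with the largest change, or 2 members where none had changed. Probe sets of predicted or unnamed transcripts were counted but not named (15 of the higher and 34 of the lower genes). Lists were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists, with an estimated correlation and fry as alternatives. Other alternatives were quantile normalization, median centring, no filter or the 50th percentile, pseudocounts of 1 and 64, the mean of a gene's probe sets, a single prior variance, a robust prior, the replicate number as a block, an adjusted p of 0.10, a 2-fold minimum, a plain test per gene, and leaving out each array in turn. A comparison of list medians with 10000 random lists matched on intensity, 4 further gene lists and the other 2 splits of the arrays were added after the data were seen. Python 3.11.15 with matplotlib 3.10.9 drew the figures.

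The test was tried on 20 simulated data sets of 13916 genes for the comparison of Ezh2 KO with wild type, each with 200 genes changed. It recovered 31.3% of the changes of 0.5 on the log2 scale, 56.2% of those of 1 and 79.0% of those of 2. Of the genes called there, 6.37% had not been changed, somewhat above the nominal level. The camera test called 0 lists in these simulations. The simulated genes varied independently of each other, with a spread drawn from the fitted prior variance. These rates therefore do not cover correlation between genes, or real data that depart from that prior.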

Results

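Gene expression was measured in mouse leukemic cells that had been transformed with the MLL-AF9 fusion gene and purified from the bone marrow of C57BL/6 recipient mice. The genotype entry of the labels gives the cells as wild type or as knockout for Ezh2, the catalytic subunit of Polycomb repressive complex PRC2, which methylates histone H3 at lysine 27. Each group held 2 samples, and each sample was hybridised to its own 1-colour Affymetrix array. The labels conflict on the knockout samples: their genotype entry names Ezh2, while another entry states that the recipients were repopulated with marrow cells lacking Ink4a and Arf. The group is called Ezh2 KO below, after the genotype entry. Nothing in the labels says that the samples of a group came from separate mice or leukemias, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

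Across 13916 genes, log2 intensities correlated at r = 0.985 between the wild-type arrays and at 0.986 between the knockout arrays, against 0.977 to 0.979 between groups. Genes are not independent replicates, so these correlations describe the arrays only. Among 4469 genes with a mean intensity above 1000, the median absolute log2 difference was 0.076 and 0.073 within the groups and 0.131 to 0.155 between them. The 3-prime to 5-prime signal ratio of the actin control lay between 1.21 and 1.26 on the 4 arrays, and that of the Gapdh control between 0.744 and 0.801. The Y-linked gene Eif2s3y had 2852 ± 56.7 intensity units in the wild type and 2836 ± 73.3 in the knockout (mean ± SD, n = 2 arrays, as for all intensities below).

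The comparison of the groups asks which transcripts differ between MLL-AF9 leukemic cells labelled wild type and those labelled Ezh2 KO. The Ezh2 transcript itself was at 5265 ± 70.0 in the wild type and 4990 ± 1.49 in the knockout, a log2 change of -0.08 (SE 0.06, limma adjusted p = 0.484). A single probe set is named for Ezh2. Its position relative to the deleted part of the gene is not known here, so this value checks nothing about the deletion or the labels.

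In total 1608 genes (11.6% of those tested) changed between the groups at a limma adjusted p under 0.05, of which 772 were higher and 836 lower in the Ezh2 KO cells. At least 2-fold changes were found in 147 of the higher and 121 of the lower genes, and the median absolute log2 change of the 1608 genes was 0.48. Their groups of arrays did not overlap in any case. Over all genes 52.5% had groups that did not overlap, where chance gives 33.3%. The balance of higher and lower calls moved when each array was centred on its median, which gave 402 higher and 1014 lower genes. Quantile normalization left it near the main result, at 749 higher and 811 lower. The number of calls rests on a prior variance that follows intensity. With a single prior variance limma called 0 genes, although 2595 had an unadjusted p under 0.05 (3462 with the trend), and a plain test per gene called 3. Leaving out wild-type replicate 1 gave 831 genes, and leaving out wild-type replicate 2 gave 1061.

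The transcript with the largest rise was Cpa3, the mast cell carboxypeptidase A3, which went from 57.7 ± 10.01 to 1279 ± 54.1 (17.7-fold, adjusted p = 7.23e-07). The basic helix-loop-helix factor Tcf24 rose from 1127 ± 114 to 9618 ± 7.62 (8.45-fold, adjusted p = 8.58e-08). Next came Stag3, a cohesin subunit of meiotic cells, at 6.91-fold, the retinol carrier Rbp4 at 6.35-fold, and Cdk5rap1, an enzyme of tRNA modification, at 6.26-fold. The phosphoinositide 3-kinase adaptor Pik3ap1 rose 6.25-fold, the Src family kinase Yes1 6.03-fold, the elongation factor Ell2 5.46-fold, the BMP receptor Bmpr1a 4.62-fold and Prg2, the major basic protein of eosinophil granules, 4.58-fold. Myom1, a sarcomere protein, rose 4.39-fold and the chitinase Chit1 4.22-fold. Averaging all probe sets of a gene, including those below the filter, reduced the log2 change of Pik3ap1 from 2.64 to 1.67. It reduced that of Yes1 from 2.59 to 1.84 and that of Ell2 from 2.45 to 1.05 (adjusted p = 0.076). Ell2 had 0 further probe sets above the filter, so its average took in only probe sets below it. Ell2 was at 13.4 and 51.6 on the wild-type arrays, the first below the filter intensity of 19.96. Its log2 change ran from 3.05 with a pseudocount of 1 to 1.62 with one of 64, and was 1.85 without wild-type replicate 1 and 3.05 without wild-type replicate 2. A pseudocount of 64 reduced the log2 change of Cpa3 from 4.14 to 3.47 and that of Myom1 from 2.13 to 1.52. Chit1, at 9.43 ± 4.45 in the wild type, had a log2 change of 3.20 with a pseudocount of 1 and 1.08 with a pseudocount of 64, and lost its call without knockout replicate 2 (1.88, adjusted p = 0.0557).

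The largest fall was that of Ikzf2, which encodes the lymphoid transcription factor Helios, from 1376 ± 14.3 to 88.0 ± 13.1 (13.4-fold, adjusted p = 7.23e-07). Several genes of the interferon response followed. The guanylate-binding protein gene Gbp2 fell from 428 ± 39.7 to 30.3 ± 5.36 (9.60-fold, adjusted p = 2.45e-05), Nlrc5, the transactivator of MHC class I genes, from 454 ± 11.9 to 49.2 ± 10.4 (7.25-fold), the chemokine gene Cxcl9 6.24-fold and Gbp6 5.97-fold. Cox6b2, a testis form of a cytochrome c oxidase subunit, fell 9.47-fold, Mndal of the interferon-inducible Ifi200 family 5.96-fold and the axonemal dynein gene Dnah8 5.88-fold. The sphingosine 1-phosphate receptor gene S1pr3 fell 5.31-fold, S100a10 4.35-fold and Psma8, a proteasome subunit of the testis, 4.32-fold. The Gbp genes and Mndal have close relatives whose transcripts the probes may share, so their levels are less certain. Cxcl9 and Gbp6 were at 3.57 ± 0.809 and 7.45 ± 7.18 in the knockout, below the filter intensity of 19.96, and their log2 changes ran from -4.56 and -4.17 with a pseudocount of 1 to -1.34 and -1.37 with one of 64. Msantd3 also passed (log2 change -2.11), but at 8.39 ± 5.28 in the knockout, so its place among the largest falls rests on signals below the filter intensity. A further probe set of Msantd3 ran the other way: the gene had 0.80 with a pseudocount of 1, 0.52 without wild-type replicate 1 and 0.57 without wild-type replicate 2, none of these past the threshold. S1pr3 had -0.998 over the mean of its probe sets (adjusted p = 0.115) and -1.75 with a pseudocount of 64. Ikzf2 had -2.88 over the mean of its probe sets in place of -3.75, Dnah8 -1.64 in place of -2.56 and Cxcl9 -1.75 in place of -2.64. In place of -2.12, S100a10 had -1.54 over the mean of its probe sets, -1.96 with a pseudocount of 1 and -1.66 with one of 64. A pseudocount of 64 gave -2.38 for Gbp2 and -2.20 for Nlrc5, in place of -3.26 and -2.86. Psma8, at 12.97 and 38.6 on the knockout arrays, had -1.97 without wild-type replicate 1 (adjusted p = 0.0612), -2.74 with a pseudocount of 1 and -1.31 with one of 64.

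**Figure D1:**
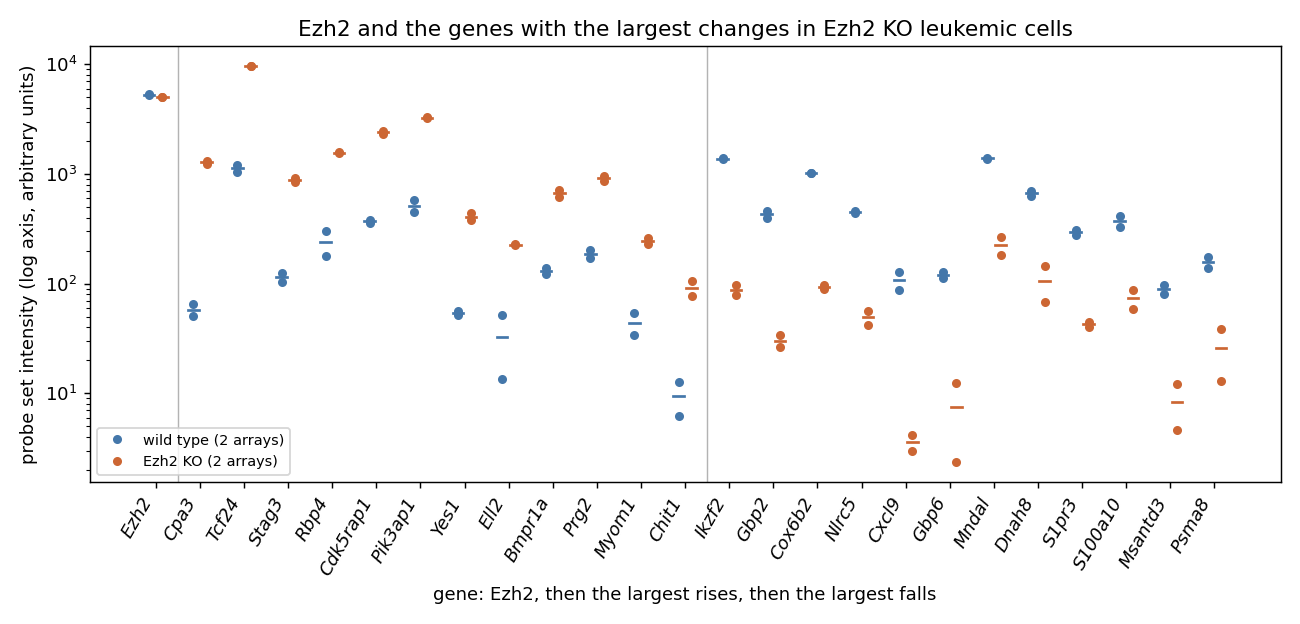
Intensity on each array (log axis, arbitrary units) of Ezh2, the 12 genes with the largest rises and the 12 with the largest falls; points are single arrays and bars are group means of 2 arrays. Ezh2 lies at 5265 and 4990 in the wild type and the knockout, Cpa3 at 57.7 and 1279, and Ikzf2 at 1376 and 88.0.

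Of 30 gene lists fixed before the data were examined, 9 shifted against the remaining genes in limma's camera test with a preset correlation of 0.01, 6 upward and 3 downward. With a correlation estimated from the data 0 lists passed, and the adjusted p of each is given beside it. Median centring moved the median log2 change of all genes from 0.007 to -0.09, which is close in size to the medians of several lists. Of the named genes 96 changed, and 48 of them also passed at every limma setting that tested them with another normalization, filter, pseudocount, probe set rule, set of arrays, robust prior or block. The single prior variance and the plain test per gene are left out of that count. For the others among the list members below, the highest adjusted p over those limma settings is given as the setting maximum.

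Immediate early genes, the transcription factors and feedback regulators induced within minutes of a stimulus, shifted upward as a list. Of 18 tested members 13 were higher and 1 lower (14 and 1 when adjusted over the list alone), with a median log2 change of 0.73 (camera adjusted p = 2.53e-12, adjusted p = 0.441 with an estimated correlation). Egr1 rose 3.76-fold from 1772 ± 77.7 to 6745 ± 927, Fosb 2.44-fold, Nr4a1 2.23-fold and the phosphatase gene Dusp1 2.11-fold from 5583 ± 15.7 to 11793 ± 546. The member that fell was Myc, from 3282 ± 24.8 to 2261 ± 67.1.

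Genes of mitosis shifted upward by a small amount as a list. All 24 tested members had a positive log2 change, with a median of 0.27, and 13 passed the threshold (17 adjusted over the list alone; camera adjusted p = 1.09e-10, adjusted p = 0.441 with an estimated correlation). Cenpf, a kinetochore protein, rose 1.39-fold, the proliferation antigen Mki67 1.35-fold, the kinesin Kif20a 1.32-fold and the ubiquitin-conjugating enzyme Ube2c 1.32-fold. The median was 0.17 with median centring. The setting maxima of these 4 genes were 0.0845, 0.0557, 0.0859 and 0.0683, for Cenpf with averaged probe sets and for the others with median centring. The DNA replication list did not pass (median -0.06, -0.084 to 0.0046 without 1 array, 0.03 with averaged probe sets, camera adjusted p = 0.184). Of its 24 tested members 3 were lower and 1 higher (5 and 1 adjusted over the list alone). Gins1, of the replicative helicase complex, fell 1.28-fold, the clamp loader subunit Rfc3 1.23-fold and thymidine kinase Tk1 1.18-fold, while the ribonucleotide reductase subunit Rrm2 rose 1.19-fold. Their setting maxima were 0.479, 0.142, 0.127 and 0.438, and each call was lost without wild-type replicate 1, at log2 changes of -0.35, -0.26, -0.25 and 0.21. Without knockout replicate 1 the calls of Rfc3, Tk1 and Rrm2 were lost too (-0.27, -0.26 and 0.23), as were those of Rfc3 and Tk1 without wild-type replicate 2 (-0.34 and -0.24) and that of Tk1 without knockout replicate 2 (-0.23).

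Targets of p53 shifted upward, with 4 of 17 tested members higher and 0 lower (7 and 0 adjusted over the list alone; median 0.38, camera adjusted p = 0.00611, adjusted p = 0.441 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, rose 1.99-fold from 195 ± 1.46 to 403 ± 1.55, the death receptor Fas 1.76-fold, Trp53inp1 1.30-fold and Mdm2, the ubiquitin ligase of p53, 1.24-fold. The last 3 had setting maxima of 0.128, 0.53 and 0.289 and lost their calls without wild-type replicate 2, at 0.45, 0.30 and 0.37. Mdm2 lost its call without wild-type replicate 1 (0.26) or knockout replicate 1 (0.28) as well, and Trp53inp1 without knockout replicate 2 (0.36). The list's median was 0.20 without wild-type replicate 1, 0.21 without knockout replicate 2 and 0.24 with averaged probe sets. Cell cycle inhibitors had 4 members higher and 2 lower of 15 (7 and 2 adjusted over the list alone) and did not pass as a list (median 0.22, 0.13 with median centring, camera adjusted p = 0.0672). The list passed with quantile normalization (camera adjusted p = 0.0350) and without a filter (camera adjusted p = 0.0408). Its median was 0.20 without wild-type replicate 2 and 0.16 without knockout replicate 1. Besides Cdkn1a, the antiproliferative genes Btg2 and Btg1 rose 1.63-fold and 1.48-fold and the stress gene Gadd45g fell 2.11-fold. Btg1 had a setting maximum of 0.0578 and a log2 change of 0.33 without wild-type replicate 1. Apoptosis regulators had 4 of 21 higher and 1 lower (5 and 1 adjusted over the list alone; median 0.10, 0.015 to 0.10 without 1 array, camera adjusted p = 0.445). Among them the BH3-only gene Bmf rose 1.65-fold and the survival gene Mcl1 1.46-fold, and Bid fell 1.26-fold, with setting maxima of 0.297 for Bmf and 0.0553 for Bid.

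Interferon-stimulated genes shifted downward as a list, with 5 of 20 tested members lower and 0 higher (6 and 0 adjusted over the list alone; median -0.37, camera adjusted p = 6.81e-05, adjusted p = 0.441 with an estimated correlation). Apart from Gbp2, the tetherin gene Bst2 fell 1.71-fold from 636 ± 3.37 to 365 ± 34.7, Gbp3 1.70-fold and Xaf1 1.69-fold. Xaf1 had a setting maximum of 0.322, with averaged probe sets. The list's median was -0.23 without wild-type replicate 1.

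Granulocyte genes moved in both directions. Genes of secondary granules and neutrophils shifted upward, with 8 of 18 tested members higher and 3 lower (11 and 4 adjusted over the list alone; median 0.44, camera adjusted p = 0.00362, adjusted p = 0.492 with an estimated correlation). The ficolin gene Fcnb rose 3.00-fold from 3916 ± 68.8 to 11803 ± 691, the gelatinase Mmp9 2.29-fold and the integrin Itgam 1.67-fold, while Anxa1 fell 1.74-fold. Mmp9 lost its call with averaged probe sets (log2 change 0.70, limma adjusted p = 0.103). Its call was also lost without wild-type replicate 1 (0.84) and without knockout replicate 1 (0.27), the latter with another of its probe sets chosen. The list's median was 0.29 without knockout replicate 1. Genes of primary granules and promyelocytes shifted downward, with 5 of 14 lower and 1 higher (6 and 2 adjusted over the list alone; median -0.08, mean -0.29, camera adjusted p = 0.0239, adjusted p = 0.586 with an estimated correlation). The cytotoxic granule gene Nkg7 fell 3.32-fold, the histidine decarboxylase Hdc 2.56-fold and the myeloid factor Cebpa 1.54-fold, and Igsf6 rose 1.30-fold with a setting maximum of 0.114. The granule enzyme genes Mpo, Elane and Prtn3 did not pass, at log2 changes of 0.09, -0.03 and 0.05. The median was -0.16 without knockout replicate 1 and -0.02 without knockout replicate 2, and -0.18 with median centring. The list lost its call with the filter at the 50th percentile (adjusted p = 0.0578) and against random lists matched on intensity, a comparison added after the data were seen (adjusted p = 0.301).

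Monocyte and macrophage genes also split, with 6 of 18 higher and 7 lower (the same numbers adjusted over the list alone; median -0.11, -0.20 with median centring, camera adjusted p = 0.285). The median was -0.08 without knockout replicate 1 and -0.02 without knockout replicate 2. Lysozyme Lyz2 and the lipopolysaccharide co-receptor Cd14 each rose 1.94-fold, Cd14 from 1612 ± 127 to 3139 ± 12.6. The adhesion receptor Vcam1 fell 3.47-fold from 5293 ± 673 to 1509 ± 97.6 and the lysosomal protease Ctss 2.31-fold. Lyz2 shares sequence with Lyz1, so the probes may read both. The basophil, mast cell and eosinophil list did not pass (3 of 9 higher and 1 lower, 4 and 2 adjusted over the list alone; median 0.52, camera adjusted p = 0.184). It depended on single arrays, with a median of 1.10 without wild-type replicate 1, 0.07 without wild-type replicate 2 and 0.34 without knockout replicate 2. It passed with median centring (camera adjusted p = 0.0254). Its higher members were Cpa3, Prg2 and Prg3, the last a further eosinophil granule protein that rose 2.51-fold, and its lower member was Hdc.

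The list of MLL-AF9 target genes shifted upward, with 6 of 18 members higher and 1 lower (9 and 1 adjusted over the list alone; median 0.19, camera adjusted p = 0.0136, adjusted p = 0.568 with an estimated correlation). Its lower member was Myc, named above among the immediate early genes, at a log2 change of -0.53. The helix-loop-helix genes Id2 and Tcf4 rose 1.52-fold and 1.37-fold and Mef2c 1.34-fold, with setting maxima of 0.0618 for Id2 and 0.0864 for Mef2c, the latter without wild-type replicate 1 at 0.37. The list's call was lost without wild-type replicate 1 (median 0.11, adjusted p = 0.169), with median centring (0.095) and with averaged probe sets. WNT and TGF-beta signalling genes shifted upward, with 4 of 20 higher and 0 lower (4 and 0 adjusted over the list alone; median 0.13, camera adjusted p = 0.0191, adjusted p = 0.462 with an estimated correlation). Besides Bmpr1a, the BMP target Id1 rose 1.58-fold, the receptor Tgfbr1 1.35-fold and Smad1 1.31-fold. Tgfbr1 and Smad1 had setting maxima of 0.137 and 0.186, the latter at 0.34 without knockout replicate 1, and Smad1 also lost its call without wild-type replicate 1 (0.44) or 2 (0.35). The median was 0.25 without knockout replicate 2, 0.03 with median centring, 0.07 without a filter and 0.31 with the filter at the 50th percentile. Against the random lists it did not pass (adjusted p = 0.336).

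Genes of oxidative phosphorylation shifted downward by a small amount as a list. All 29 tested members had a negative log2 change, with a median of -0.12, and 2 passed the threshold (5 adjusted over the list alone; camera adjusted p = 6.81e-05, adjusted p = 0.441 with an estimated correlation). The median was -0.22 with median centring. Cycs, cytochrome c, fell 1.20-fold and the complex I subunit Ndufb5 1.18-fold, with setting maxima of 0.214, at -0.17 without wild-type replicate 2, and 0.189, at -0.19 without wild-type replicate 1. Ndufb5 also lost its call without wild-type replicate 2 (-0.29) or knockout replicate 1 (-0.22). Glycolysis genes did not pass as a list (1 of 15 higher and 3 lower, 1 and 4 adjusted over the list alone; median -0.06, -0.087 to -0.0052 without 1 array, camera adjusted p = 0.35). The glucose transporter Slc2a3 rose 2.13-fold, and the phosphofructokinases Pfkp and Pfkl and the pyruvate kinase Pkm fell 1.53-fold, 1.52-fold and 1.22-fold. Pfkp had a setting maximum of 0.507, with averaged probe sets. Pfkl lost its call with averaged probe sets (-0.08, limma adjusted p = 0.796). Without wild-type replicate 1 (-0.10) or 2 (-0.09) another probe set of Pfkl was chosen, and the call was lost too. Pkm lost its call without wild-type replicate 2 (-0.23). Ribosomal protein genes had 0 of 18 past the threshold by limma over all genes and over the list alone, a median of 0.01 (-0.067 to 0.070 without 1 array), a mean of -0.01 and a downward camera direction (adjusted p = 0.743). Rpl14 had a log2 change of -0.23 and Rps6 one of -0.18, which was -0.10 without knockout replicate 1.

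**Figure D2:**
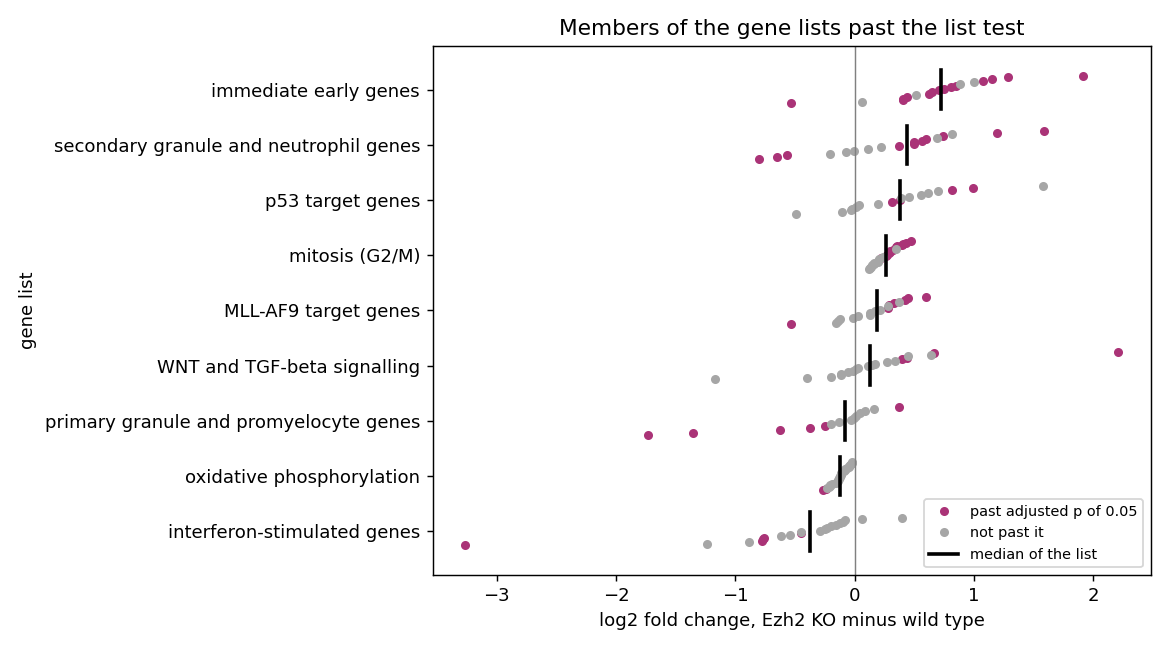
Log2 fold change (horizontal axis, knockout minus wild type, 2 arrays per group) of the tested members of the 9 lists past the camera test with a preset correlation; each point is a gene and the black bar is the list's median. The medians run from -0.37 for interferon-stimulated genes to 0.73 for immediate early genes, and mitosis genes all lie above 0.

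Among the subunits of PRC2, 1 of 11 passed (1 adjusted over the list alone; median 0.04, 0.017 to 0.071 without 1 array, camera adjusted p = 0.537). It was Jarid2, an accessory subunit, which rose 1.27-fold, with a setting maximum of 0.131 and a log2 change of 0.28 without wild-type replicate 2. The related methyltransferase Ezh1 had a log2 change of 0.09 and did not pass. In PRC1, the Polycomb complex that ubiquitinates histone H2A, 3 of 15 subunits were higher and 0 lower (4 and 0 adjusted over the list alone; median 0.12, 0.02 with median centring, camera adjusted p = 0.153). The PRC1 gene Pcgf2 was not tested because its mean was below the filter. It was at 43.4 ± 10.8 in the wild type and 3.29 ± 0.158 in the knockout. Without a filter the PRC1 list had a median of 0.11 (camera adjusted p = 0.333). The PRC1 list had a median of 0.07 without knockout replicate 1 and 0.10 without knockout replicate 2. Bmi1 rose 3.29-fold from 2400 ± 112 to 7923 ± 57.9 (adjusted p = 7.23e-07), Phc1 2.42-fold and the ubiquitin ligase Rnf2 1.55-fold. Phc1 had a setting maximum of 0.066 and a log2 change of 0.83 without wild-type replicate 2, and Rnf2 had 0.281 with averaged probe sets. Of the histone H3 lysine 27 and lysine 4 modifiers 4 of 29 were higher and 0 lower (6 and 1 adjusted over the list alone; median 0.07, 0.012 to 0.063 without 1 array, camera adjusted p = 0.184). The lysine 4 demethylases Kdm5b and Kdm5a rose 1.42-fold and 1.22-fold, the methyltransferase Kmt2c 1.38-fold and the lysine 27 demethylase Kdm6b 1.34-fold. The calls of Kdm5b, Kdm5a and Kdm6b, with setting maxima of 0.635, 0.431 and 0.152, were each lost without wild-type replicate 1, at 0.57, 0.28 and 0.45. They were also lost without wild-type replicate 2 (0.44, 0.30 and 0.39) and without knockout replicate 1 (0.34, 0.25 and 0.46), and that of Kdm6b without knockout replicate 2 (0.38).

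Developmental transcription factors chosen as textbook Polycomb targets had 0 of 33 tested members past the threshold by limma over all genes and over the list alone (median 0.07, -0.087 to 0.21 without 1 array, camera adjusted p = 0.661). The array held 64 of these genes, and those not tested were below the filter. With the filter at the 50th percentile fewer than the 4 members needed for a list test remained. Most signals were thus dim, and the result does not show that these genes stayed unchanged. The LIM factor Lhx9 had a log2 change of 1.03 (SE 0.42, adjusted p = 0.165) and Wt1 one of -0.996 (SE 0.52, adjusted p = 0.276), both at mean intensities of 50.2 or lower. With pseudocounts of 1 and 64, Lhx9 was at 1.56 and 0.50 and Wt1 at -1.82 and -0.45. Wt1 was at -1.54 without knockout replicate 1 and -0.46 without knockout replicate 2. Posterior and non-A Hox genes had 1 of 8 lower (1 adjusted over the list alone; median 0.02, -0.074 to 0.31 without 1 array, mean -0.13, camera direction upward with adjusted p = 0.863). That gene was Hoxa11, 2.86-fold lower, with log2 changes of -2.14 and -0.84 at pseudocounts of 1 and 64. It lost its call without a filter (limma adjusted p = 0.0883). The call was also lost without wild-type replicate 1 (-1.32), wild-type replicate 2 (-1.71) or knockout replicate 2 (-1.07). Fetal and oncofetal genes had 2 of 11 higher and 0 lower (2 adjusted over the list alone; median 0.07, -0.19 to 0.29 without 1 array, camera adjusted p = 0.6). The zinc finger gene Bcl11a rose 4.20-fold from 25.3 ± 12.8 to 154 ± 14.2 and Arid3a 1.33-fold. Bcl11a depended on the probe set chosen. Averaging probe sets gave a log2 change of 0.88 (limma adjusted p = 0.14). The change was 0.19 without knockout replicate 1 and 1.07 without knockout replicate 2, where another of its probe sets was chosen. Arid3a had 0.29 without knockout replicate 1 (adjusted p = 0.0546) and 0.34 without wild-type replicate 2 (adjusted p = 0.106). Stem and progenitor genes had 2 of 15 higher and 1 lower (4 and 1 adjusted over the list alone; median 0.10, 0.028 to 0.18 without 1 array, camera adjusted p = 0.184). Mycn rose 1.48-fold and the ETS factor Erg 1.28-fold, while Sox4 fell 1.32-fold. Averaging probe sets gave log2 changes of 0.02 for Mycn, 0.40 for Erg and 0.005 for Sox4, with adjusted p of 0.976, 0.226 and 0.995. The calls of Erg and Sox4 were also lost without wild-type replicate 1, at 0.36 and -0.33, and without wild-type replicate 2, at 0.36 and -0.48. Erg lost its call without knockout replicate 2 (0.31) and Sox4 without knockout replicate 1 (-0.30).

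Markers of other marrow cell types were mostly dim, and none of their lists passed at the main setting. Erythroid genes had 0 of 8 past the threshold over all genes and over the list alone (median 0.22, -0.11 to 0.27 without 1 array, camera adjusted p = 0.705), with Ermap at -1.002 and Hemgn at 0.87. Ermap was at -0.46 without knockout replicate 1 and -1.55 without knockout replicate 2, and Hemgn at 0.32 without wild-type replicate 1. With pseudocounts of 1 and 64, Ermap was at -1.85 and -0.44. Stroma and endothelium genes had 0 of 14 on both counts (median 0.06, -0.051 to 0.14 without 1 array, camera adjusted p = 0.863), with Pdgfrb at 0.92 and Lum at -0.73. Pdgfrb was at 0.52 without knockout replicate 2 and 0.44 with averaged probe sets, and Lum at -1.25 and -0.32 with pseudocounts of 1 and 64. Megakaryocyte and platelet genes had 2 of 12 higher (2 adjusted over the list alone; median 0.17, camera adjusted p = 0.117). That list passed with the filter at the 50th percentile (median 0.55, camera adjusted p = 0.00565) and with median centring (median 0.08, camera adjusted p = 0.0403). Its median was 0.44 without knockout replicate 2. The higher members were the tetraspanin Cd9, 2.59-fold, and the factor Nfe2, 1.17-fold. Nfe2 had a setting maximum of 0.503. It had no call without any 1 of the 4 arrays, at log2 changes from 0.21 to 0.24. B cell genes had 1 of 10 lower (1 adjusted over the list alone; median -0.05, -0.23 to 0.13 without 1 array, camera adjusted p = 0.652), the immunoglobulin heavy chain gene Ighm, which fell 1.45-fold. Ighm lost its call over the mean of its probe sets (-0.01, setting maximum 0.99). T and NK cell genes had 1 of 6 higher (1 adjusted over the list alone; median 0.38, 0.23 to 0.50 without 1 array, camera adjusted p = 0.223). It was Bcl11b, from 59.4 ± 4.64 to 183 ± 17.6. Its call was lost without knockout replicate 1 (0.88) or knockout replicate 2 (0.80), where another of its probe sets was chosen. Averaging probe sets gave 0.83 (limma adjusted p = 0.0666). Dendritic cell genes had 2 of 10 lower and 0 higher (2 and 1 adjusted over the list alone; median 0.04, -0.13 to 0.081 without 1 array, mean -0.01, camera direction downward with adjusted p = 0.681). Beside Bst2, the MHC class II gene H2-Ab1 fell 2.01-fold from 221 ± 18.0 to 104 ± 28.8, with a setting maximum of 0.104 at -0.93 without wild-type replicate 2, and no call without wild-type replicate 1 (-1.08) or knockout replicate 2 (-0.76). Adhesion and marrow homing receptors had 5 of 17 higher and 3 lower (5 and 4 adjusted over the list alone; median 0.04, -0.060 to 0.12 without 1 array, mean -0.05, camera direction upward with adjusted p = 0.681). The integrin Itgb2 rose 1.24-fold, with a setting maximum of 0.206 and 0.27 without wild-type replicate 2 (adjusted p = 0.0932). The endothelial and leukocyte ligand Icam2 fell 1.64-fold from 2130 ± 108 to 1295 ± 82.4.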

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

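All of the tests in this part were chosen after the data were seen. Probe sets outside the named genes were fitted with limma in the same way, and their signals in the Ezh2 KO arrays were compared with those of the wild-type arrays. Among 5242 tested probe sets that are not in the gene table, 205 were higher and 65 lower in the knockout. Among 708 probe sets that carry several gene symbols, 20 were higher and 55 lower. The probe sets with 1 gene symbol had 1000 higher and 951 lower calls, so the balance differed from theirs in both kinds (two-sided Fisher's exact p = 6.30e-15 and 2.87e-05, with probe sets that are not independent). Median centring gave 110 higher and 71 lower calls for the first kind, 9 higher and 55 lower for the second, and 464 higher and 971 lower for probe sets with 1 symbol. The median intensities of the 3 kinds were 69.7, 645 and 255. Their median log2 changes over all tested probe sets were 0.12, -0.01 and 0.02. The first and dimmest kind was thus shifted upward as a whole, and its excess of higher calls cannot be told apart from that shift.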

How the results depend on the processing

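The comparison with random lists was chosen after the data were seen, and the remaining alternatives before. The Ezh2 change stayed between -0.17 and -0.05 and short of the threshold at every setting run. The count of changed genes (1608) stayed within 1.5 times under quantile normalization, median centring, both filters, both pseudocounts and the robust prior. Median centring gave 402 higher genes. Averaging probe sets gave 1028 genes (477 higher, 551 lower), a single prior variance 0 (0 and 0, with 2595 at an unadjusted p under 0.05), a 2-fold minimum 268 (147 and 121), and a plain test per gene 3 (0 and 3); the 2-fold minimum removes small changes by construction, and the cause of the others was not tested. Relaxing the adjusted p to 0.10 gave 2388 genes. Leaving out 1 array, with the lone sample assumed to vary like the other group, gave 831 to 1641 genes (472 to 733 higher, 359 to 910 lower) and 9 to 13 lists. With the replicate number as a block, 2719 genes changed (1282 higher, 1437 lower), including all 1608; same-numbered arrays deviated together at r = 0.04 over all genes and 0.22 over bright genes, and with 2 pairs and no label on a shared batch this does not settle whether the numbers pair the arrays. The block also brought PRC1 subunits and cell cycle inhibitors past the threshold.

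An estimated correlation left 0 lists, with unchanged medians of 0.73 for immediate early, 0.27 for mitosis, -0.12 for oxidative phosphorylation, -0.37 for interferon-stimulated, 0.44 for secondary granule, 0.38 for p53, 0.19 for MLL-AF9, 0.13 for WNT and TGF-beta and -0.083 for primary granule genes. Fry called 11 lists one-way, without MLL-AF9 targets and primary granule genes but with cell cycle inhibitors, monocyte, PRC1 and stem cell genes, and 26 in either direction. Against random lists, primary granule genes (adjusted p = 0.301) and WNT and TGF-beta genes (adjusted p = 0.336) did not pass, while basophil, mast cell and eosinophil genes (0.00771) and cell cycle inhibitors (0.0135) did. The MLL-AF9 list had medians of 0.095 with median centring, 0.15 with averaged probe sets and 0.11 to 0.20 without 1 array, and primary granule genes did not pass with the 50th percentile filter (-0.083, adjusted p = 0.0578). The causes were not tested.

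Some lists that did not pass turned direction, and none passed where it turned. Posterior Hox genes had a median of -0.071 with quantile normalization and -0.074 to 0.31 without 1 array. Stroma had -0.041 with quantile normalization and 0.12 with averaged probe sets, and adhesion -0.055 with median centring, 0.042 with fry and -0.060 to 0.12 without 1 array. The ranges without 1 array were -0.087 to 0.21 for developmental factors, -0.19 to 0.29 for fetal, -0.11 to 0.27 for erythroid and -0.067 to 0.070 for ribosomal genes. Against random lists the median was 0.0079 for ribosomal and 0.045 for dendritic genes. Where a median keeps its sign, the turn is that of the test. Msantd3 turned to 0.80 with a pseudocount of 1 and ran from -2.34 to 0.57 without 1 array, where another of its probe sets was chosen, and Sox4 turned to 0.0050 with averaged probe sets. Genes below an intensity of 19.96 were not separated from background.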

Other observations

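The tests of array exchange, probe position, Ink4a and Arf, other cells, MHC haplotype and RNA quality were chosen after the result was seen, and those of interferon-gamma activity and handling stress before the values they use were looked at. The list of MHC class I antigen presentation genes was itself drawn up after its members' values had been seen. Of its 17 tested members 14 were lower and 0 higher in the Ezh2 KO cells (median log2 change -0.71). The class I heavy chain gene H2-K1 fell 2.30-fold from 15885 ± 169 to 6909 ± 21.3 (limma adjusted p = 2.90e-06), H2-M3 3.21-fold and beta-2-microglobulin, B2m, 1.61-fold. The immunoproteasome genes Psmb8 and Psmb9 fell 2.12-fold and 2.14-fold and the peptide transporter Tap1 2.04-fold. The general chaperones of the pathway, Canx, Calr and Pdia3, did not pass, at -0.04, 0.01 and -0.07. Class I heavy chain genes resemble each other, so the share of each in these signals is uncertain.

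A different MHC haplotype that the probes read less well would spare the 9 members encoded elsewhere. Their median was -0.52, and 6 of them, such as B2m and Psmb10 (-0.68, SE 0.07), lay more than 2 of their own SE below -0.1. A first bound, set on that median against the spread between members (SE 0.29), had not been met and was replaced. The list was drawn up after its members' values were seen, so falling members were partly chosen. These values speak for those 6 members only and are no test of the list as a whole. For the 8 members encoded in the MHC (median -1.06) a haplotype cannot be told apart, since class I and other genes there fell together. Fewer cells of another type in the knockout samples cannot be told apart either. Of 15 markers 7 were tested, with a median of 0.13, and only 3 had a wild-type mean of 100 or more, too few to decide. Among these H2-Ab1 fell, while H2-Aa (-0.23) and Cd74 (0.13) did not pass. Of the monocyte genes named above, Vcam1 and Ctss fell and Lyz2 and Cd14 rose. Lower interferon-gamma type activity is a hypothesis. In a further set of interferon-gamma induced GTPase genes, 6 tested genes had a median of -0.98, with 5 lower, among them Gbp7 (2.33-fold) and Irgm2 (2.52-fold). The related genes Gbp2, Gbp3 and Gbp6 had already been seen to fall. A fall of this set was therefore likely beforehand and is weak support. Whether the genotype or the surroundings of the cells would set interferon-gamma type activity stays untested.

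The Ezh2 transcript was near the same level in both groups. An exchange of one wild-type and one Ezh2 KO array is argued against by the other 2 splits of the arrays, in which limma called 0 genes (at most 265 at an unadjusted p under 0.05) against 1608 as labelled. The probe set may lie outside the deleted part of the gene, which cannot be told apart with 1 probe set of unknown position. The cells labelled Ezh2 KO could lack Ink4a and Arf instead, as one label entry reads, and this stays open too, since their gene Cdkn2a was already at 21.8 in the wild type and at 31.6 in the knockout. A loss of Ezh2 protein was not measured here.

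The upward shift of immediate early genes may reflect stress during cell handling, but heat shock and unfolded protein genes did not rise with them. Their median log2 change was -0.070, with 0 of 13 higher and 4 lower. The standard error across these 13 genes was 0.063, which describes the spread between genes and not between arrays. Genes are not independent replicates. The lack of a rise argues against stress that also induces heat shock genes, and a delay or warming that acts on immediate early genes alone was not tested. The 3-prime to 5-prime signals of the actin and Gapdh controls differed between group means by at most 0.036 on the log2 scale. Single arrays of a group differed by 0.106, a measure that is wider than a difference of means by construction. These values argue against a large difference in RNA quality at these 2 controls. A smaller difference, or one that acts on other transcripts, was not tested. An effect of the genotype stays open and untested.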
